A study of Homo sapiens with 3 samples.

How the data were processed

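RNA was sequenced from 3 cultures of MCF7, a human breast cancer cell line that carries the estrogen receptor. The labels name 1 control library and 2 libraries from separate RBM45 knockdown cell lines, called line 1 and line 2 here. Per the labels' protocols, the cells grew at 37 °C and 5% CO2 in medium with 10% serum and 0.01 mg/ml insulin. RNA was taken up in TRIzol and cleaned on columns, and 4 µg of total RNA entered each library, which was made with standard Illumina protocols. Whether the libraries kept strand, how rRNA was removed, the hairpin sequences and what the control cells carried are not given in the sources used here. Libraries were grouped by the genotype label alone.

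The authors deposited whole-number counts per gene for each library, with no normalization. The submitters' processing notes name Bowtie2 2.0.6, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff 2.1.1, without saying which step made which file. The program that counted reads and the genome build are not given in the sources used here. All 58735 gene IDs in each file, with their start and end positions, were found in GENCODE release 29, so coordinates below are on GRCh38. Every row named a gene. Total counts were 18208893 in the control, 18769715 in line 1 and 17495702 in line 2. Genes with at least 1 count numbered 24404, 24797 and 24712.

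The deposited FPKM values (counts scaled by gene length and library size) were tested against the deposited counts. In each library every FPKM equalled the gene's count divided by its length and by 1 constant per library. That constant was 0.981 of the total count in the control, 0.998 in line 1 and 1.00 in line 2. The FPKM values therefore carried no measurement beyond the counts and served only as an alternative, on the log2(FPKM + 1) scale. Such a scale understates the change of genes with low values.

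Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 16858, libraries were scaled with TMM (factors 0.989, 1.00 and 1.01), and dispersions were estimated over all genes. The quasi-likelihood test (glmQLFit with legacy = FALSE, then glmQLFTest) set both knockdown lines against the control. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 1 residual degree of freedom, which came wholly from the difference between the knockdown lines. The lone control was assumed to vary as those lines do, so a p-value does not measure the spread between control cultures. The prior had 12.6 degrees of freedom, and the biological coefficient of variation was 9.66%.

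Each line was also set against the control as log2 CPM (counts scaled to the effective library size, prior count of 2). These are differences of 1 library against 1, without a test, and they were described by a size rule of 2-fold. Because both lines share the control, 50 pairs of unchanged lines were simulated against 1 control. Every gene was given the fitted common dispersion of 0.00933. Shared copies of 1 library were looked for by a chi-square of each pair of libraries over genes. Its value per degree of freedom was 8.24, 11.7 and 8.29, so no library was a copy of another.

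A set of 30 gene lists with 742 members was fixed before the data were examined. Of the members, 732 matched by symbol, 7 by an older symbol, and 3 by a symbol held by several IDs, of which the ID with most reads was used. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives. Each list's median in each line was also ranked among 10000 random lists matched on expression. The rule for named genes was fixed at the same time. It takes RBM45, IFNB1 and IRF7, and the 10 genes higher and 10 lower with the largest change in the line that changed less. Those genes needed an adjusted p under the threshold and 5 CPM in both lines (higher) or the control (lower). Where fewer than 10 passed, genes meeting the other criteria filled the places. The rule adds up to 4 called members per list, or 2 of the highest expression where none was called, and 5 genes on each side between the lines. Genes that share reads with near-identical copies are called uncertain.

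Intervals on single counts are exact Poisson intervals, and intervals on ratios of 2 counts are exact (Clopper-Pearson) binomial intervals, at 95%. A floor of 3 counts served only to mark values too low to read, and counts of 0 were kept as 0. Both kinds of interval cover counting error only, since reads without molecular identifiers are not independent molecules.

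The test was tried on simulated counts for these 16858 genes and 3 libraries, with 200 changed genes in each of 5 runs. The changed genes were drawn from those with a mean of at least 5 CPM. All genes had the same dispersion and varied independently. The rates below may therefore not hold for genes with fewer counts or more spread, or for lists of correlated genes. It called 35.8% of genes changed 1.5-fold, 95.2% of genes changed 2-fold and 100% of genes changed 4-fold. Of 860 calls, 42 (4.88%) were false. A list of 30 genes raised together had a camera p under 0.05 in 5 of 5 runs and an unchanged list in 0 of 5.

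Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma voom, other settings of the quasi-likelihood test, other prior counts and size rules, the FPKM values, and leaving out each knockdown line. A GC and length correction and the summing of near-identical copies were chosen after seeing the data. GC content was known for 16850 of the 16858 genes. Sequence words were counted in the GENCODE 29 transcripts with Python 3.11.15.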

Results

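The series set out to learn how the loss of RBM45, an RNA-binding protein, alters gene expression in breast cancer cells. Its title ties that loss to reduced SUMOylation of IRF7, a transcription factor of the interferon response, and to transcription of IFNB1, the gene of interferon beta. MCF7 cells with RBM45 knocked down were compared with control MCF7 cells by RNA sequencing. The data comprised 1 control library and 1 library from each of 2 knockdown lines, with 17495702 to 18769715 counts per library. Between-line SDs below have n = 2, the control has no replicate, and p-values measure only the spread between the 2 lines.

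RBM45 (ENSG00000155636, chromosome 2, 178112424 to 178139011 on GRCh38) was lower in both knockdown lines. The control held 283 counts, or 15.7 CPM (95% Poisson interval 14.0 to 17.7). Line 1 held 180 counts, or 9.59 CPM (8.24 to 11.1), and line 2 held 152 counts, or 8.61 CPM (7.30 to 10.1). These levels were 60.9% of the control in line 1 (95% interval 50.3 to 73.7) and 54.7% in line 2 (44.6 to 66.9), beyond counting error in each. The ratio of line 1 to line 2 was 1.11 (0.893 to 1.39), so the lines did not differ beyond counting error. The fitted change was -0.79 on the log2 scale (SE 0.20), with an adjusted p of 0.307 in edgeR's quasi-likelihood test, which did not pass the threshold over all genes.

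**Figure D1:**
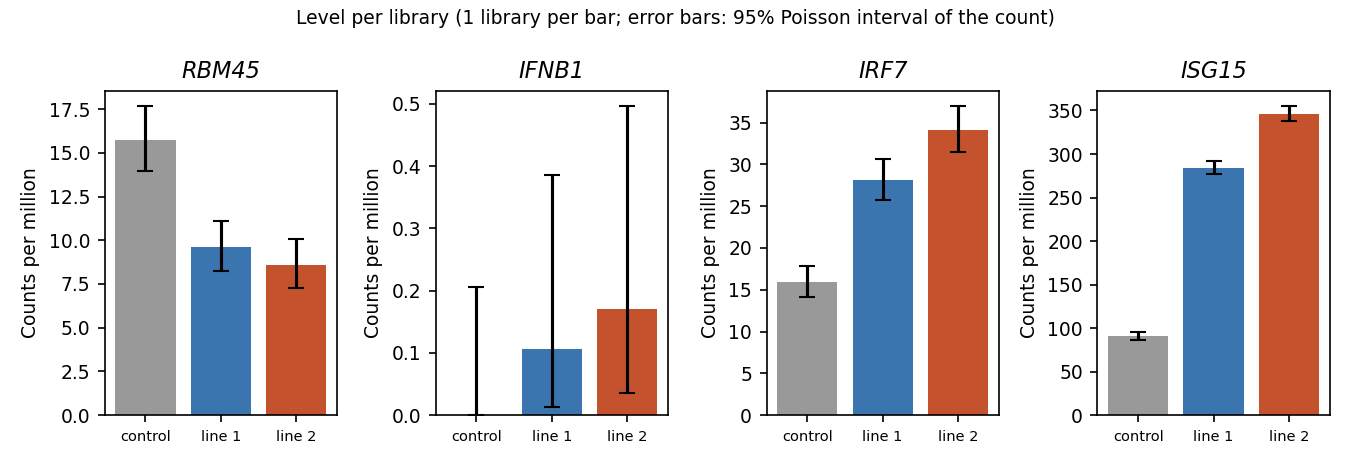
Levels in CPM of RBM45, IFNB1, IRF7 and ISG15 in the control library and the 2 knockdown lines, 1 library per bar, with exact 95% Poisson intervals of the count. RBM45 stood at 15.7 CPM in the control and at 9.59 and 8.61 CPM in the lines, IRF7 at 15.9 against 28.1 and 34.2 CPM, and ISG15 at 91.3 against 284.1 and 346.4 CPM, while the IFNB1 bars rest on 0, 2 and 3 counts.

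The next question was whether IFNB1 and IRF7 transcripts differed after knockdown. IRF7 (ENSG00000185507, chromosome 11, 612553 to 615999) rose from 15.9 CPM in the control to 31.1 ± 4.29 CPM (SD, n = 2) in the knockdown lines. It stood at 177% of the control in line 1 (95% interval 153 to 205) and 215% in line 2 (186 to 248). Its log2 change was 0.97 (SE 0.18) with an adjusted p of 0.0410 in edgeR. That call sat near the threshold. It was lost with DESeq2 (adjusted p = 0.107), with library totals in place of TMM (0.128) and with no filter on low counts (0.775), and over all alternatives the adjusted p ran from 0.00685 to 0.775. IFNB1 (ENSG00000171855, chromosome 9, 21077105 to 21077963) had 0 counts in the control, 2 in line 1 and 3 in line 2. All 3 values are at or under the floor of 3 counts, so no fold was computed, and a difference in IFNB1 was not detectable at this depth.

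Other type I and type III interferon genes were also sparse. Of 20 fixed genes, 2 had enough counts for a test, and neither passed it over all genes. IFNL3, a type III interferon (interferon lambda), had 0, 16 and 15 counts in the control, line 1 and line 2 (edgeR adjusted p = 0.313, and 0.00357 when adjusted over the 2 tested genes alone). IFNL2 had 2, 10 and 8 counts and was too sparse for a test. IFNL3 shares 52.4% of its 31-base words with another gene and is uncertain. IFNL1 had 4, 9 and 16 counts (adjusted p = 0.856). Every listed IFNA gene had 0 counts in all 3 libraries.

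The widest difference between knockdown and control lay in interferon-stimulated genes, the effectors that cells switch on when they sense interferon. Of 51 tested members of that list, 30 rose, none fell, and all 51 were higher than the control in both lines. The largest fitted changes were those of IFI44L (5.66-fold, from 3.50 to 19.9 ± 6.84 CPM, SD, n = 2) and IFI44 (5.29-fold, from 3.23 to 17.2 ± 5.94 CPM). IFI27, a mitochondrial protein induced by interferon, rose 3.84-fold from 8.51 to 32.7 ± 0.608 CPM. IFI6, which is abundant, rose 3.78-fold from 132.9 to 502.6 ± 118 CPM. ISG15, the ubiquitin-like modifier, rose 3.45-fold from 91.3 to 315 ± 44.1 CPM. RSAD2 (viperin) rose 3.70-fold to 17.1 ± 3.34 CPM, OAS2, which makes 2'-5' oligoadenylates, 3.53-fold to 33.0 ± 4.14 CPM, and DDX60, a helicase, 3.47-fold to 83.8 ± 10.3 CPM. BST2 (tetherin) rose 3.30-fold to 53.5 ± 0.411 CPM, and SAMD9 3.56-fold to 8.93 ± 0.347 CPM. Adjusted p-values of these 10 genes in edgeR ran from 4.51e-05 (ISG15) to 0.0152 (SAMD9).

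Adjusted over the list alone, 47 of the 51 genes rose. The mean change of the list was 1.16 on the log2 scale, or 2.24-fold (camera adjusted p = 3.59e-40). With an estimated correlation the adjusted p was 0.623, and fry gave an adjusted p of 0.388. Both rest on the single residual degree of freedom and passed none of the lists, so they do not tell lists apart. The list's median was 0.93 in line 1 and 1.15 in line 2, each above all 10000 random lists matched on expression. In 44 of the 51 genes line 2 was higher than line 1, with a median difference of 0.23. Markers of immune and blood cells did not move with the list. Only 3 of 13 were abundant enough to test, PTPRC had 0 counts in every library, ITGAM stood at 4.28, 4.05 and 4.36 CPM and CD8A at 4.06, 3.89 and 3.80 CPM (list adjusted p = 0.843).

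Over all 16858 genes, 34 rose and 6 fell at the adjusted threshold in edgeR, and each of the 40 had the same sign in both lines. Line 2, set apart in the same way from the control and line 1, gave 156 calls, 28 of them interferon-stimulated, and line 1 gave 10. The line 2 fit had a prior of 16860 degrees of freedom against 12.6 for the control, so its count of calls is not comparable. That split also pools line 1 with the control, so a gene raised alike in both lines can be called for line 2. BST2 (16.2, 53.8 and 53.2 CPM in the control, line 1 and line 2) and IFI27 (8.51, 33.1 and 32.3 CPM) were such calls. The 28 are therefore not a set particular to line 2. Of the 34, 30 were the interferon-stimulated genes above, and their fitted folds ran from 1.73 to 5.66 with a median of 2.74. HLA-C belonged to the antigen presentation list. The other 3 lay outside the lists and are named here after their values were seen. They were PARP10 (3.35-fold, 23.8 to 79.6 ± 20.1 CPM), HELZ2 (81.2 to 162.5 ± 6.12 CPM) and the pseudogene GTF2IP1 (3.34-fold), which is uncertain because 97.9% of its 31-base words also occur in another gene. Summed with GTF2I and GTF2IP4, GTF2IP1 had a log2 change of 0.42 and did not pass the threshold (edgeR adjusted p = 0.424). At an unadjusted p under 0.05, 596 genes were higher and 422 lower, against 843 expected by chance over both directions together. With no filter on low counts, edgeR and limma voom called 0 genes and DESeq2 called 30 higher and 3 lower. At an unadjusted p under 0.05 that edgeR fit still had 436 genes higher, 46 of them interferon-stimulated, and 378 lower.

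**Figure D2:**
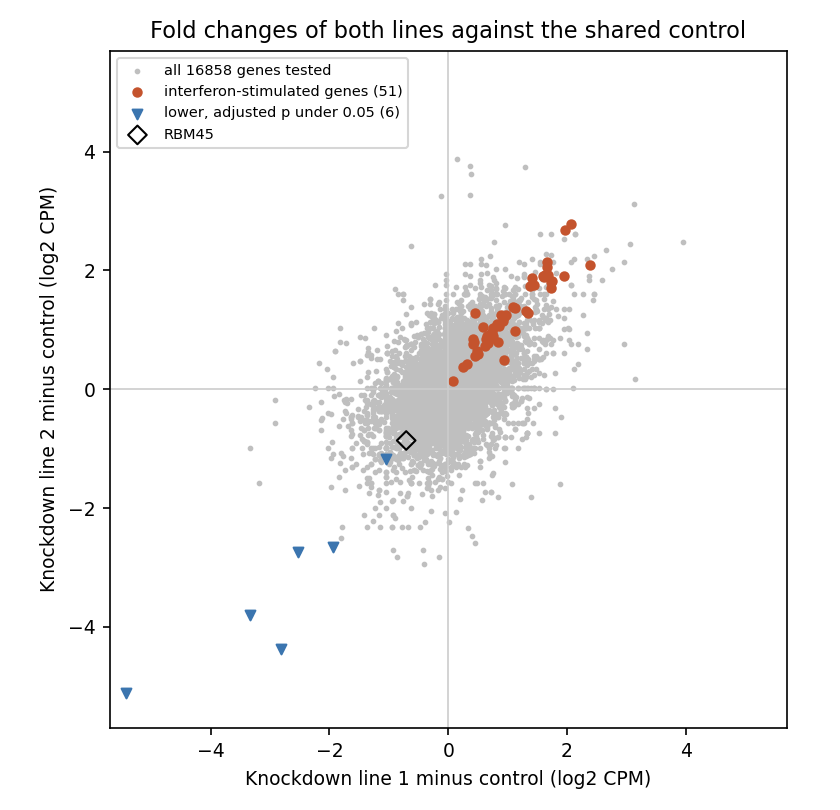
Log2 CPM differences from the control for line 1 (horizontal) and line 2 (vertical), 1 point per gene for 16858 genes. The 51 interferon-stimulated genes all lie at the upper right of the plot, and the 6 genes past the threshold with lower levels lie in the lower left, down to -5.43 and -5.12 for BOLA2B. RBM45 lies at -0.71 and -0.86.

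Each of the 6 genes that fell is uncertain. BOLA2B fell from 39.0 CPM in the control to 0.799 and 1.02 CPM in the lines (edgeR adjusted p = 6.19e-08). CBSL fell from 6.95 to 0.586 and 0.397 CPM, U2AF1, a splicing factor that binds the 3' splice site, from 36.1 to 9.33 and 5.66 CPM, and CKMT1B, a mitochondrial creatine kinase, from 18.9 to 9.06 and 8.27 CPM. The remaining calls were RN7SL5P (3.28 to 0.480 and 0.397 CPM) and the pseudogene PKD1P1 (2.17 to 0.213 and 0 CPM), which are outside the rule for named genes and were chosen after their values were seen. All 6 shared at least 50% of their 31-base words with another gene, as did 936 of the tested genes (5.55%) and 1 of the 34 that rose. When the counts of CBSL, U2AF1 and CKMT1B were summed with those of CBS, U2AF1L5 and CKMT1A, the changes were -0.54, -0.50 and -0.75 on the log2 scale and no longer passed the threshold (adjusted p = 0.807, 0.911 and 0.173). The U2AF1 sum hid a split between the lines, with 723 counts in the control, 872 in line 1 and 182 in line 2. BOLA2B summed with BOLA2 stayed at -5.35 (adjusted p = 5.65e-08). With copies summed, 3 genes were lower at the threshold.

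Among genes with at least 5 CPM in the control that were lower in both lines without passing the threshold, those ranked highest by the line that changed less are given as values. ITGB3BP, a centromere protein, had 7.89 and 7.59 CPM in the lines, 51.8% of the control in the fit (adjusted p = 0.136). RIBC2 was at 48.9%, FST, which encodes the activin antagonist follistatin, at 56.3%, and the pseudogene SERBP1P5 and AC093157.1 at 57.2% and 56.3%, with edgeR adjusted p-values of 0.570 to 0.697. SERBP1P5 shares 56.6% of its 31-base words with another gene and is uncertain. RBM45 itself was at 57.9%.

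By the 2-fold rule, 191 genes were higher in both lines and 68 were lower, of which 26 and 4 had at least 5 CPM. The higher genes included 21 interferon-stimulated genes. Simulated unchanged lines against a shared control gave means of 47.0 and 15.5 genes, at most 60 and 22 in 50 draws. Independent lists of these sizes (420 higher and 285 lower in line 1, 539 and 295 in line 2) would share 13.4 and 4.99. The counts moved with the handling of genes near the floor. They were 86 and 5 with at least 1 CPM in 2 libraries, and 522 and 765 with no filter. Across genes, which are not independent replicates, the log2 ratios of the lines had a Pearson r of 0.510 and a Spearman rho of 0.473, against a simulated r of 0.501 with no effect. Their covariance was 0.0993 against a simulated 0.0549 (0.0522 to 0.0578 over the draws), a difference of 0.0444. Without the interferon-stimulated list the covariance was 0.0947. The simulation gave every gene the same dispersion, so genes that vary more would also raise the counts and the covariance above it. Nor could the control be split. The share of this excess owed to that library, to such noise or to the knockdown is therefore not known.

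Genes that present antigen on MHC class I were higher as a group. Of 19 tested, 1 rose, 8 rose when adjusted over the list alone, and 17 were higher in both lines. The mean change was 0.53 on the log2 scale, or 1.45-fold (camera adjusted p = 5.80e-09; adjusted p = 0.623 with an estimated correlation). HLA-C, the member that rose, went from 48.0 to 87.5 ± 13.5 CPM (1.82-fold, edgeR adjusted p = 0.0244), although reads of HLA genes can be split among close relatives. Among 20 genes of nucleic acid sensing and IRF signalling, 3 rose, also adjusted over the list alone. They were IRF7 and the cytosolic RNA sensors DDX58 (RIG-I, 30.3 to 63.0 ± 4.08 CPM, adjusted p = 0.00230) and IFIH1 (MDA5, 44.8 to 77.3 ± 8.54 CPM, adjusted p = 0.0325), all of them interferon-stimulated as well. The list mean was 0.29 and the median 0.12 (camera adjusted p = 0.00884; adjusted p = 0.623 with an estimated correlation). NF-kB and inflammatory targets had a mean of 0.27 (camera adjusted p = 0.00903; 0.623 with an estimated correlation) with 0 of 17 called, also over the list alone. NFKBIA, the inhibitor of NF-kB, was at 168.8 CPM in the control and 181 ± 14.6 CPM in the lines.

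The title names SUMOylation of IRF7. Genes of the SUMO pathway, a list that does not cover the proteins SUMO is attached to, did not pass the list test. None of 23 passed the threshold in either direction, also over the list alone, and the list mean was -0.01 on the log2 scale (camera adjusted p = 0.684), with the sign turning under library totals (0.02) and upper-quartile scaling (0.01). TRIM28 stood at 875 CPM in the control and 798 ± 21.9 CPM in the lines, and SUMO3 at 280 and 257 ± 9.19 CPM. Transcript levels do not measure the SUMOylation of a protein.

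Proliferation genes were lower by small amounts. All 30 genes of the G1/S and DNA replication list were lower than the control in both lines. None passed the threshold over all genes, and 8 fell when adjusted over the list alone. The list mean was -0.30 on the log2 scale, or 0.812 of the control (camera adjusted p = 2.20e-09; adjusted p = 0.623 with an estimated correlation). MCM4, a subunit of the replicative helicase, had 441 CPM in the control and 352 ± 6.77 CPM in the lines, and MCM7 had 468 and 410.3 ± 29.7 CPM. Of 30 G2/M and mitosis genes, 24 were lower in both lines, none was called, also over the list alone, and the mean was -0.18 (camera adjusted p = 0.000189; 0.623 with an estimated correlation). MYBL2 stood at 399 CPM and 346 ± 21.5 CPM, and MKI67 at 478 and 458 ± 29.2 CPM. Replication-dependent histone genes went the other way. Of 16 tested, 14 were higher in both lines, none was called, also over the list alone, and the mean was 0.32 (camera adjusted p = 0.000305; 0.623 with an estimated correlation). HIST1H2BK was at 64.7 CPM and 79.5 ± 6.34 CPM, and HIST2H2BE at 50.7 and 53.2 ± 11.5 CPM. HIST1H2BK shares 86.3% of its 31-base words with another gene and is uncertain.

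A further 5 lists were lower by small amounts, with no call of a member except U2AF1. Splicing factors and nuclear RNA-binding proteins had a mean of -0.22 and a median of -0.13 (camera adjusted p = 0.000189), with 24 of 30 lower in both lines. Cytosolic ribosomal proteins had a mean of -0.09 (0.00211), with 58 of 74 lower in both lines. Nucleolar and MYC target genes had a mean of -0.12 (0.0107), with 16 of 22 lower. Nuclear-encoded genes of the respiratory chain had a mean of -0.09 (0.0239) and mitochondrially encoded mRNAs -0.19 (0.00928). For each of these 5 lists the adjusted p was 0.623 with an estimated correlation. The mitochondrial mRNAs went mainly with line 2, at a median of -0.33 against -0.08 in line 1, and mitochondrial genes took 5.57% of counts there against 6.75% in the control and 6.46% in line 1. With a GC and length correction the respiratory chain mean went from -0.09 (SE over members 0.02) to -0.07 (SE 0.02) and its adjusted p to 0.0828, and the mitochondrial mean from -0.19 (SE 0.05) to -0.12 (SE 0.05) and 0.0532, so both lists lost their calls as their means shrank. RPS2 was at 2850 CPM in the control and 2761 ± 99.1 CPM in the lines, NPM1 at 1407 and 1216 ± 30.1 CPM, ATP5F1B at 884 and 814.6 ± 21.4 CPM, and MT-CO1, which is uncertain because it shares 66.7% of its words, at 14910 and 13510 ± 1102 CPM.

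**Figure D3:**
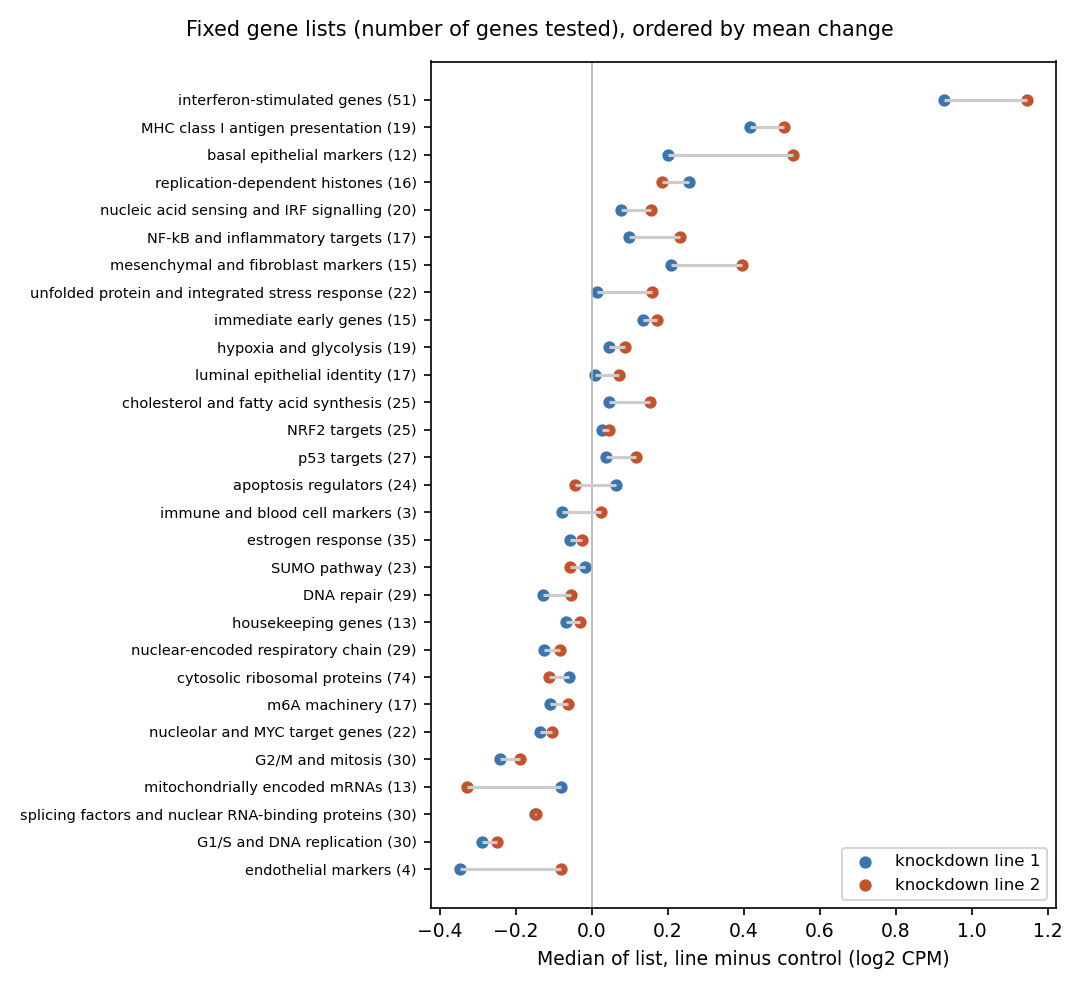
Median log2 difference from the control over the tested members of each of 29 gene lists, in line 1 (blue) and line 2 (orange), ordered by the mean of both lines. Interferon-stimulated genes lie at 0.93 and 1.15, MHC class I genes at 0.42 and 0.51, and G1/S genes at -0.29 and -0.25.

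Estrogen response and luminal lists did not pass the list test. None of 35 estrogen response genes passed the threshold, also over the list alone (camera adjusted p = 0.523). GREB1, an estrogen receptor target, was at 1303 CPM in the control and 1116 ± 122 CPM in the lines. Luminal markers had a mean of 0.10 (0.168) and 1 of 17 higher over the list alone. KRT8 stood at 11200 and 11560 ± 315 CPM. Basal markers had a mean of 0.44 on the log2 scale (camera adjusted p = 0.00184; 0.623 with an estimated correlation), with none of 12 called and 1 higher over the list alone. They went mainly with line 2, at a median of 0.53 against 0.20 in line 1. CDH3 (P-cadherin) was at 195.6 CPM in the control and 227 ± 18.7 CPM in the lines. Mesenchymal and fibroblast markers had a mean of 0.25 (0.0740) and endothelial markers -0.35 (0.207, 4 tested). Over the list alone, 1 of 15 mesenchymal genes rose.

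No other list passed the list test, and none of their members was called over all genes. Over the list alone, 1 stress response gene and 1 hypoxia gene rose. Their camera adjusted p-values were 0.296 for p53 targets (CDKN1A at 342 and 405 ± 58.1 CPM), 0.883 for apoptosis regulators, 0.128 for the unfolded protein and integrated stress response, 0.168 for hypoxia and glycolysis, and 0.116 for cholesterol and fatty acid synthesis. They were 0.130 for DNA repair, 0.166 for the m6A machinery, 0.418 for NRF2 targets, 0.143 for immediate early genes and 0.168 for housekeeping genes, of which ACTB was at 4545 CPM in the control and 4648 ± 44.6 CPM in the lines.

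The 2 knockdown lines were then set against each other, 1 library against 1 and without a test. In 780 genes they differed at least 2-fold. Among genes with 5 CPM or more, the largest differences in favour of line 2 were SIK1, a salt-inducible kinase (0.278 CPM in the control, 0.320 in line 1 and 5.61 in line 2), and PRODH, a proline dehydrogenase (1.22, 1.12 and 12.6 CPM). SPCS2P4, a pseudogene, followed with 4.84, 2.56 and 15.9 CPM, then TH (2.78, 1.55 and 5.21 CPM) and S100A2 (4.45, 3.68 and 10.5 CPM). Line 1 was higher in U2AF1L5 (4.12, 37.1 and 4.65 CPM), MZT1 (34.0, 27.9 and 8.16 CPM), MEMO1P1 (1.72, 9.17 and 2.83 CPM), SERF1B (6.84, 11.4 and 3.57 CPM) and RHBDL1 (4.34, 6.87 and 2.21 CPM). U2AF1L5, SPCS2P4, MEMO1P1, SERF1B and SIK1 share 73.2% to 98.2% of their 31-base words with another gene and are uncertain. MZT1, which recruits gamma-tubulin complexes, was lowest in line 2.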

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

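The tests of GC content, immune cells and the control for the interferon-stimulated genes, of single copies for the genes that fell, and of scaling for the proliferation genes were chosen after the results were seen, as were RN7SL2 and MALAT1.

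The higher level of interferon-stimulated genes in both lines rests, like each comparison here, on a single control library. A GC and length correction left 34 of these genes past the threshold, against 30 without it, which argues against such a trend as the whole cause. Immune cells in the cultures are argued against by their own markers, whose 13 summed levels were higher in line 2 by 0.0205% of the summed rise of the interferon-stimulated genes and lower in line 1 (-0.0420%). What stays open is whether the control library, or the construct the cells carry, differs for reasons other than RBM45. The knockdown lines differed from each other by a median of 0.23 on the log2 scale over these genes, but no second control library exists here to set beside that, so this explanation and the loss of RBM45 cannot be told apart.

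The genes that fell share a technical trait. All 6 have at least 50% of their 31-base words in another gene, against 5.55% of tested genes (exact hypergeometric p = 2.89e-08), as read sharing between near-identical genes would give. Words were counted because near-identical copies had been seen among these same calls. The p therefore describes the overlap and is not an independent test. For U2AF1 in line 1 the partner is visible, since U2AF1L5 gained 123% of the CPM that U2AF1 lost. In U2AF1 in line 2, CBSL in line 1, and BOLA2B and CKMT1B in both lines, the other listed copy gained at most 6.74% of the loss, which argues against a plain transfer to that copy. CBS gained 47.8% of the CPM that CBSL lost in line 2, within counting error of either reading, and reads discarded at mapping, which leave no trace in these tables, stay open.

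Replication genes were lower and histone genes higher in both lines, although both groups are usually made in the same phase of the cell cycle. The choice among scalings is argued against, since the replication mean nearest to 0 under the 3 other scalings was -0.28 on the log2 scale. The TMM factors (0.989, 1.00 and 1.01) were nearly equal, so changing the scaling could move a mean only slightly. An error that all of these scalings share was not tested. A GC and length correction left it at -0.29 and the histone mean at 0.34, both past the list test at the preset correlation. More RNA without poly(A) tails in the knockdown libraries, which could raise histone transcripts, stays open, because the 27 small nuclear and nucleolar RNAs (medians -0.55 in line 1 and -0.46 in line 2) lie near the floor with a median of 12 counts in the control. The abundant RN7SL2 had 1609, 1749 and 3160 counts and MALAT1 3301, 5729 and 3632, each higher mainly in 1 line. Neither list held with an estimated correlation, but no list did with 1 residual degree of freedom. That test therefore says nothing particular about the replication and histone lists.

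Several results had opposite signs in line 1 and line 2. These differences between single libraries were not tested, and such splits are common. They occurred in 31.6% of tested genes and in 33.0% of simulated unchanged genes, against 22 of the 86 genes named by the rule. Below, each value is the log2 level in line 1 minus that in line 2. It was -3.37 for PRODH, -2.59 for SPCS2P4, -1.68 for TH, -1.48 for S100A2, 1.64 for SERF1B and 1.59 for RHBDL1. Among list members it was 0.69 for CAV1, -0.65 for FN1, 0.44 for HIST2H2BE, -0.38 for SLC7A5, -0.26 for HSPA5, 0.22 for MYC, 0.20 for G6PD and -0.20 for ALKBH5. It was 0.15 for MCL1, -0.15 for ESAM, -0.13 for MKI67, 0.11 for SOD2, -0.11 for HSP90B1, -0.10 for ITGAM, 0.0739 for SCD and 0.0406 for KRT18. List medians, as line 2 minus line 1, differed in sign for apoptosis regulators (-0.0741) and for immune and blood cell markers (0.10).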

How the results depend on the processing

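The GC and length correction and the summing of copies were chosen after seeing the data. RBM45 stayed lower under all 16 alternatives (log2 -0.86 to -0.57) and short of the threshold in those with a test (adjusted p 0.170 to 1). IRF7 stayed higher (log2 0.82 to 1.10). It missed the threshold with DESeq2 (log2 0.97, adjusted p = 0.107). In edgeR it also missed with library totals (log2 0.99, adjusted p = 0.128) and no filter (log2 0.96, adjusted p = 0.775). Genes called higher numbered 59 with at least 1 CPM in 2 libraries and 29 to 39 under the others, no filter aside. With no filter edgeR called 0 higher, 0 lower and 0 interferon-stimulated genes. There the prior had 2.98 degrees of freedom against 12.6, voom called 0, DESeq2 called 30 and 3, and the unadjusted counts were 436 and 378. Genes called lower numbered 3 with library totals, with DESeq2 and with copies summed, the last because the partner's reads were added. DESeq2 shared 34 and voom 40 of edgeR's 40 calls.

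The genes beyond the size rule in both lines numbered 601 higher and 272 lower at 1.5-fold, 14 and 4 at 4-fold, 522 and 765 with no filter, and 86 and 5 with at least 1 CPM. With prior count 0.5, 116 were lower, and with prior count 5, 101 were higher and 26 lower. FPKM gave 42 higher and 71 lower on the log2(FPKM + 1) scale, with or without a minimum of 1 FPKM, and 647 and 1030 on the log2(FPKM + 0.1) scale. In single lines 420 to 539 were higher and 285 to 295 lower. The correlation of the lines was 0.553 with at least 1 CPM, 0.494 with FPKM + 0.1 and 0.522 with at least 1 FPKM. Camera with an estimated correlation and fry called 0 lists each against 13. The interferon-stimulated mean stayed at 1.16 (adjusted p = 0.623 and 0.388). Where not stated, the cause was not tested. Of the other values with a test, list means kept their side of the threshold in 223 cases, lost it in 26 and gained it in 3, and named genes kept it in 892 and lost it in 27. Values short of the threshold in both the main fit and the alternative count as kept. These totals are therefore not a rate for called results. With a line left out and no test, 11 values of named genes moved beyond the spread of the lines and 157 did not, nor did any list mean. No result turned its direction past the threshold. No paired analysis was possible because the groups share only replicate number 1. Depth limits IFNB1 and the other interferon genes, which have few counts.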

Other observations

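The tests of shared 3' UTR words in the lines and of type II interferon genes were set before their results were seen, except the word tests against the control and the test of interferon lambda, which came after.

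Type III interferon genes were the interferon genes with the most reads. IFNL1, IFNL2 and IFNL3 summed to 6 counts in the control, 35 in line 1 and 39 in line 2. The lines stood at 5.59 times the control (95% interval 2.33 to 16.3) and 6.62 times (2.78 to 19.1), which is beyond counting error but has no replicate of the control. Tested as 1 gene, the sum had a log2 change of 2.58 (SE 0.65) and an adjusted p of 0.292 in edgeR, so whether these genes may drive the interferon-stimulated genes stays open. Genes selective for type II interferon did not settle its part either. Of 17 such genes 7 could be tested, none was called, and 6 were higher in both lines. Their mean log2 change was 0.64 (SE over members 0.19), within its error of 0.58, which is 50% of the mean of the interferon-stimulated genes. GBP2 had 195, 331 and 338 counts and SOCS1 53, 95 and 98, both of which type I interferon can also induce, while HLA-DRA had 0, 0 and 7 and CXCL9 had 0 in each library.

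Line 2 carries a sequence signature of its own. A hairpin can lower transcripts other than its target through short matches to its seed, so every 7-base word in annotated 3' UTRs was tested for lower levels in 1 line, over 10337 genes and 16188 words, with UTR length, GC content and expression in the model and interferon-stimulated genes left out. The word GAATATT stood out in line 2 against line 1 with a t of 10.8, while the strongest word in 100 shuffles reached 5.10 (permutation p = 0.0099, the smallest they can give). The 2068 genes with the word had a median log2 difference of -0.07 between the lines, against 0.02 for the 8269 without it. Against the control their median was -0.08 in line 2 and -0.02 in line 1, while genes without it were at 0.00 and -0.02. Of 94 genes at least 1.5-fold lower in line 2 than in line 1, 45 (47.9%) had the word, against 2068 of all 10337. These medians and shares are raw, without the UTR length, GC content and expression terms of the model. GAATATT was picked as the strongest word on the difference between the lines, so its median and share there are not a separate test. The comparison of line 2 with the control uses the same line 2 library, so it is not a separate test either. Of the tested genes with the word, the 7 furthest below line 1 in line 2, named after their values were seen, were MZT1 (34.0, 27.9 and 8.16 CPM in the control, line 1 and line 2), SERF1B (6.84, 11.4 and 3.57 CPM, uncertain), PDHX (48.4, 43.0 and 16.9 CPM), LCLAT1 (34.0, 26.6 and 11.3 CPM), UHMK1 (156.4, 159.0 and 77.1 CPM), ZNF891 (4.73, 6.82 and 3.46 CPM) and RMND5A (79.2, 80.8 and 42.3 CPM). The next, PGR (24.2, 48.2 and 25.4 CPM), was higher in line 1 and not lower in line 2 than in the control.

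GAATATT occurs once in the annotated RBM45 transcripts, in the coding part of exon 5 (chromosome 2, 178121320 to 178121326, GRCh38), as a hairpin against RBM45 would need. That alone is weak, since 23.2% of the tested words occur there. The t of 10.8 is consistent with seed off-targets of the line 2 hairpin, as a hypothesis, since the hairpin sequences are not given in the sources used here. Line 1 had no such word against line 2 (highest t 4.33, permutation p = 0.109). Against the control its highest word, GCTGGTC, had a t of 7.13 (permutation p = 0.0099) but is absent from the RBM45 transcripts, so a word can pass the shuffles for other reasons. The word GTGCCTT, lower in the control than in line 2, reached 4.82 (permutation p = 0.0495) and does occur in them, in a direction that no hairpin against RBM45 would give, so both criteria can be met without one. In all, 6 such tests were run. In tests on simulated data a planted word that lowered its genes by 0.1 was recovered in 5 of 5 runs. Interferon-stimulated genes were higher in line 1 as well, where this word had no such signature.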
